A study of Serendipita indica with 12 samples.

How the data were processed

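The samples were 12 one-colour Agilent microarrays of Piriformospora indica (also called Serendipita indica), a basidiomycete fungus that lives as an endophyte in plant roots. Per the labels, the fungus was grown on roots of Arabidopsis thaliana Columbia-0 and sampled 3 and 14 days post inoculation (dpi), on roots of barley cultivar Golden Promise sampled at 14 dpi, and without a plant on 1/10 PNM agar for 3 days. Each of these 4 groups had 3 arrays, which the labels call independent biological repetitions. Arabidopsis plants were 14 days old and barley germlings 3 days old at inoculation, Arabidopsis roots of many plants were pooled per sample, and barley samples came from the differentiation zone of the root. Cy3-labelled cRNA was made from 200 ng total RNA per the labels' protocols. Groups were taken from the sample titles and source names. A time entry among the sample characteristics disagreed with the titles for the colonised samples, and the titles were followed.

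The authors' scanner files gave an intensity per spot, per the file headers made with Agilent Feature Extraction 10.7.3.1, while the submitters' processing notes name version 10.5. The processed signal used here was background-subtracted and detrended within each array and not normalized between arrays, per the file headers. Medium replicate 3 was extracted with a manual-grid protocol, per the file headers, and the other arrays with the standard gene expression protocol. The authors also deposited a series table of log2 values for 12092 fungal probes and 472 control features. Its sorted columns differed from the first by at most 0.00145, with a median of 8.90 in each, and followed the scanner signals with a Spearman correlation of at least 0.99968 across probes, so the table was read as quantile-normalized log2 signal. It was used only as an alternative.

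The array held 12636 probes for 11741 loci of the fungus and 27385 probes for Arabidopsis loci. 11110 fungal loci had 1 probe and 631 had several, whose log2 values were averaged. Loci are named as in the files, which pair them with no gene name or product, so the gene lists planned by product description could not be made and were not run. A fungal gene was tested if a probe was well above background, by the scanner software's flag, on all 3 arrays of at least 1 group, which left 10030 genes. Signals at or below 1 were set to 1 before log2. Spots with an outlier flag, between 40 and 102 of 54057 on each array, were left out where another spot of the probe remained. No probe was saturated. Each array was scaled by subtracting its 75th percentile of log2 signal. Because under 50% of probes were detected on the medium and barley arrays, the percentile was taken over the 5608 probes well above background on all 12 arrays, 125 of which were Arabidopsis probes. A difference between groups is therefore relative to the commonly detected fungal transcripts of the same array and does not measure how much fungus was present.

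Differences were fitted in R 4.3.3 with limma 3.58.1 (lmFit, and eBayes with an intensity trend) over all 4 groups in a single fit, so that the groups shared an estimate of the spread. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 and an absolute log2 difference of at least 1. Files were read with data.table (version 1.17.8), and plots were drawn with matplotlib 3.10.9. Colonised roots gave little fungal signal, so dim genes had no usable level on some arrays. Calls are given first for genes measured in both groups, with a probe well above background on all 6 arrays. A gene measured on all arrays of only 1 group was compared with the lowest detected signal of the other group's arrays (or its own signal there, where higher). If this bound lay on the wrong side, the call had no order. A gene detected on only some arrays of a group was counted as partly measured. On simulated arrays with the real spread and 200 changed genes among 10030, the recovered share ran, across the 5 comparisons, from 37.5% to 47.5% at a log2 change of 1, from 85.0% to 100% at 2, and was 100% at 3. Between 1 and 3 of 9830 unchanged genes were called. Values were drawn for each gene independently around its mean, with no background floor and no plant RNA. These shares therefore do not cover errors from either.

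The comparisons, the test, the thresholds, the rule for named genes and most alternatives were fixed before the data were examined. By that rule the text names, per comparison, the genes with the largest rises and falls among called genes measured in both groups whose replicates did not overlap, limited to 2 in each direction because the files give no gene names. It also names 8 loci under the names they are believed to have in the literature on this fungus: PIIN_02023 (AMT1, an ammonium transporter), PIIN_03211 (FGB1, a beta-glucan binding lectin), PIIN_05872 (DLD1), PIIN_08944 (a secreted effector candidate), PIIN_01005 (E5NT, an ecto-nucleotidase), PIIN_02121 (a nuclease), PIIN_05825 (WSC3, a WSC-domain lectin) and PIIN_03008 (TEF, a translation elongation factor used as a reference gene). These names were given from general knowledge and checked against no annotation or genome, and that of TEF is especially unsure. Genes measured on only 1 side are given as counts.

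The Arabidopsis probes were a second, unplanned measurement. After 1545 Arabidopsis probes (5.64%) well above background on any medium array had been left out, 19172 Arabidopsis loci were tested between 14 and 3 dpi over the 6 Arabidopsis arrays, scaled by the 75th percentile of the 18798 probes detected on all 6 and fitted in the same way. On data simulated in the same way for 19172 genes, with the same limits, 30.0% of changes of 1 log2 and 97.5% of changes of 2 log2 were recovered, with 0 of 18972 unchanged genes called. 8 short lists of marker genes were written after the array was found to hold Arabidopsis probes and before any of them was tested: jasmonate- and ethylene-linked defence, salicylate-linked defence, pattern-triggered immunity, indole glucosinolate and camalexin, phosphate starvation, nitrogen uptake and assimilation, endodermis and suberin, and photosynthesis as a marker of shoot tissue. Their symbols were assigned from general knowledge of the locus numbers. Lists with at least 5 tested members were tested with limma's camera, with a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists. In a simulation with independent genes 3 of 3 shifted lists and 0 of 3 unshifted lists were called.

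The 6 Arabidopsis arrays shared slide 1, with the time points in different rows of it. The barley arrays and medium replicates 1 and 2 shared slide 3, in different rows of it, and medium replicate 3 was on slide 2. Arabidopsis and medium, or Arabidopsis and barley, never shared a slide. Barley against medium could be fitted with slide as a fixed block, and the other comparisons across slides with slide as a random block (duplicateCorrelation with statmod 1.5.0, consensus correlation 0.193). The alternatives covered the probe set for scaling, quantile normalization, normexp background correction with an offset of 50 on the median spot and background signals (the mean spot signal was not used here), the authors' deposited table, filters on dim genes, the choice of probe, outlier spots, the variance model, the arrays in the fit, replicate and slide blocks, the threshold, and each array left out in turn. Scaling to all probes adds a constant per array, set by the Arabidopsis probes. It moved every fungal difference by -9.15, -7.12 and -1.68 log2 for Arabidopsis at 3 dpi, Arabidopsis at 14 dpi and barley against medium, by 2.03 between the Arabidopsis times and by 5.44 between barley and Arabidopsis. Relative to these constants no difference between groups changed. Quantile normalization moved the median gene measured in both groups by 0.08, -0.09, -0.20, -0.10 and -0.15 in the same order, and normexp by 0.22, 0.10, 0.13, -0.16 and 0.05.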

Results

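RNA from the fungus Piriformospora indica was measured on 12 arrays, 3 for each of 4 conditions: on Arabidopsis roots at 3 and 14 dpi, on barley roots at 14 dpi, and alone on agar medium at 3 dpi. The design compared fungal gene expression during root colonisation with growth without a plant, between early and late colonisation, and between hosts. On medium 85.2% ± 2.25 (SD, n = 3) of the fungal probes were well above background. On Arabidopsis roots the share was 50.2% ± 4.64 at 3 dpi and 73.5% ± 2.31 at 14 dpi, and on barley roots it was 66.4% ± 5.26. The median signal of fungal probes detected on every array was 32.8-fold below medium on Arabidopsis at 3 dpi, 5.91-fold below at 14 dpi and 12.5-fold below on barley, and it rose 5.54-fold between the Arabidopsis times. The same unscaled median also varied within groups, from 12.19 to 13.35 log2 among the medium arrays. The array's Arabidopsis probes were well above background for 74.8% ± 0.600 at 3 dpi and 75.7% ± 0.150 at 14 dpi, against 2.98% ± 0.400 on barley and 3.13% ± 0.455 on medium. Only fungal genes are compared in this part, though 125 of the 5608 probes used for scaling were Arabidopsis probes. The 3 arrays per group limit the precision of each comparison.

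**Figure D1:**
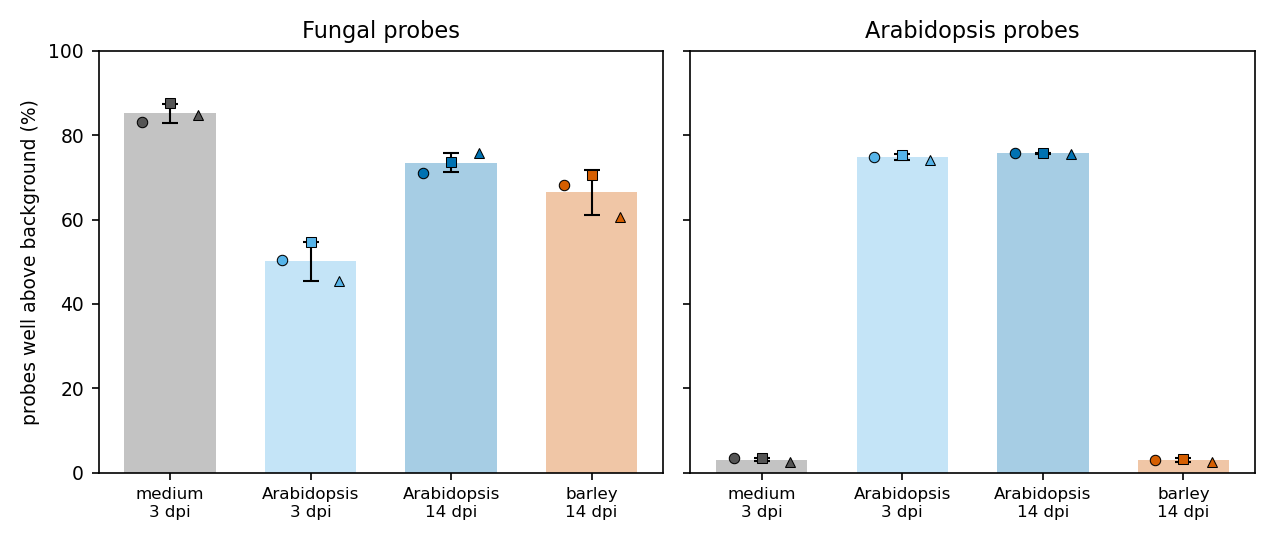
Percent of fungal probes (left) and Arabidopsis probes (right) well above background on each array (symbols: circle, square and triangle for replicates 1, 2 and 3; bars: mean; error bars: SD, n = 3). Fungal probes averaged 85.2% on medium and 50.2% on Arabidopsis at 3 dpi, and Arabidopsis probes stayed near 3% on medium and barley.

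All 3 arrays detected 9917 fungal genes on medium, 5567 on Arabidopsis at 3 dpi, 8605 on Arabidopsis at 14 dpi and 7372 on barley, and 5364 genes were detected on all 12 arrays. Over these 5364 genes, barley separated from every other condition on the first principal component (56.9% of the variance), where the barley arrays lay between 62.0 and 64.6 and all others at -6.55 or below. Arabidopsis at 3 dpi stood apart on the second (19.3%), between 32.5 and 39.8 with all others at 3.81 or below. Arrays of a group correlated at 0.948 to 0.994 and arrays of different groups at 0.604 to 0.878 across genes, which are not independent replicates. The median SD of a gene was 0.19 log2 on medium, 0.09 and 0.19 on Arabidopsis at 3 and 14 dpi, and 0.19 on barley.

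**Figure D2:**
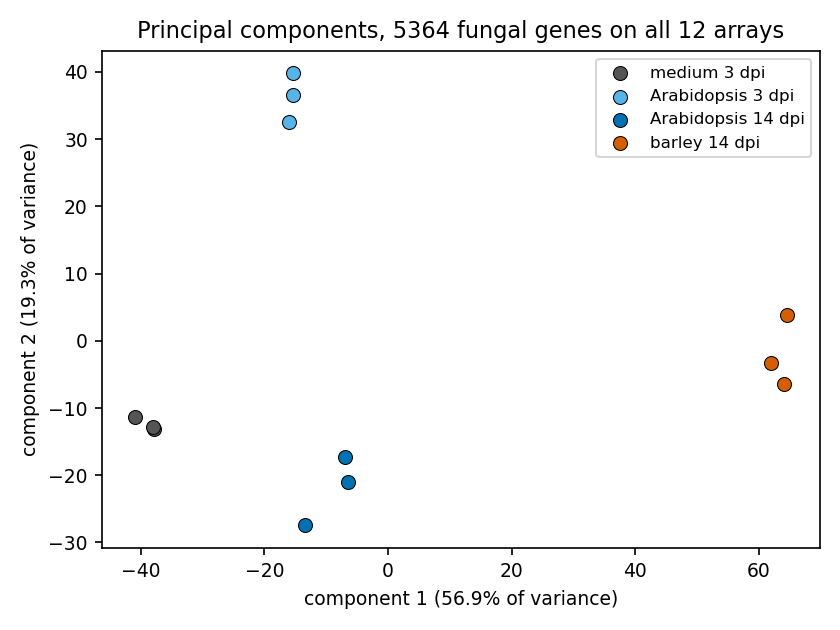
The first and second principal components of normalized log2 signal over the 5364 fungal genes detected on all 12 arrays, with a point per array and a colour per group. Barley arrays lie at 62.0 to 64.6 on component 1 and Arabidopsis 3 dpi arrays at 32.5 to 39.8 on component 2.

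Early colonisation was addressed by comparing the fungus on Arabidopsis at 3 dpi with the fungus on medium at the same age. The ecto-nucleotidase gene E5NT (PIIN_01005), whose secreted product breaks down extracellular nucleotides, was higher on the root by 1.61 log2 (SE 0.34, adjusted p = 0.00178 by limma), from -2.76 ± 0.34 to -1.16 ± 0.45 (SD, n = 3 each). The beta-glucan binding lectin gene FGB1 (PIIN_03211) stood at 0.63 ± 0.25 against 0.97 ± 0.30, a difference of -0.34 that did not pass the test. WSC3 (0.79), the effector candidate PIIN_08944 (0.61) and the nuclease gene PIIN_02121 (1.47, detected on 1 of 3 root arrays) were not called either, and AMT1 was detected on 1 of 3 root arrays at a difference of 0.21. Leaving out Arabidopsis 3 dpi replicate 3 brought the nuclease gene to 2.00 and a call, and normexp called it at 2.94, AMT1 at 1.32 and WSC3 at 1.40. With quantile normalization and in the authors' deposited table the nuclease difference was 0.32 and 0.03. PIIN_03008, taken to be the elongation factor gene TEF, was 1.67 log2 higher on the root (SE 0.19), a call that ended with quantile normalization (0.83) and in the authors' deposited table (0.58) and, like E5NT (-7.54), turned sign (-7.49) when scaling to all probes moved every gene by -9.15. Before scaling, TEF rose by 1.22 log2 from 3 to 14 dpi, against a median of 2.40 for fungal genes measured at both times. Its unscaled SD at 3 dpi was 0.13, against 0.45 for the median of fungal probes detected on every array. Arabidopsis RNA on the TEF probes therefore stays open. DLD1 was well above background on all 3 medium arrays and on none of the 9 root arrays, so no fold is given for it in any comparison.

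Among genes measured in both groups, the largest rises were 464-fold for PIIN_07267 (8.86 log2, SE 0.44) and 351-fold for PIIN_02222 (8.46, SE 0.34), and the largest falls were 13.0-fold for PIIN_10001 (-3.70, SE 0.41) and 12.1-fold for PIIN_00281 (-3.60, SE 0.23), with adjusted p between 1.4e-09 and 7.59e-06 by limma and no overlap between the 3 arrays of each group. Scaling to all probes moved every gene by -9.15 log2, which turned the sign of both of these rises. Apart from that shift, other processing moved these folds over 1.5 times for PIIN_02222 (7.56 with quantile normalization, 7.21 with normexp) and PIIN_00281 (-2.93 with normexp). Before scaling, the signals of PIIN_07267 and PIIN_02222 changed by -0.96 and -0.55 log2 from 3 to 14 dpi, while the median of the fungal genes measured at both times rose by 2.40. At 3 dpi the unscaled SD of PIIN_07267 and PIIN_02222 was 0.04 and 0.13 log2. That of the median of fungal probes detected on every array was 0.45. Arabidopsis RNA on the probes of these 2 genes therefore stays open, and their folds may not be fungal. Of 5541 genes measured in both groups, 677 were called, 473 higher and 204 lower on the root. Over all 10030 genes tested, 2212 were called, 1625 higher and 587 lower, but 1097 of these had no order at the background and 285 were only partly measured, while 11 genes were detected only on the root side and called higher and 142 only on medium and called lower. In 2171 of the 2212 the replicates of the groups did not overlap, which chance gives for 10% of genes not selected by a test, so that for called genes it adds little.

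The direction split depended on the minimum difference, on which genes entered and on the scaling. Without a minimum difference 963 genes measured in both groups were higher and 1196 lower (2263 and 2094 over all genes), and the median difference of the 5541 genes was -0.09 log2. Quantile normalization gave 434 higher and 165 lower among genes measured in both, but 775 and 1343 over all genes tested. The authors' deposited table gave 782 and 1534 over all genes, normexp 723 and 120 in both and 4197 and 148 over all, and scaling to all probes 0 and 5539 in both and 1 and 10023 over all. No slide held both groups, and with slide as a random block 663 genes measured in both were called.

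Late colonisation of Arabidopsis was compared with the same medium arrays, so host and age differed together. FGB1, which binds fungal cell wall glucan, was 27.1-fold higher at 14 dpi than on medium (4.76 log2, SE 0.56, adjusted p = 1.3e-05 by limma), at 5.73 ± 1.53 (SD, n = 3). Its difference was 5.64 without Arabidopsis 14 dpi replicate 3 and 4.17 in the authors' deposited table. The nuclease gene PIIN_02121 was 11.9-fold higher (3.57, SE 0.65; 2.96 without Arabidopsis 14 dpi replicate 2, 4.28 without replicate 3), the ammonium transporter gene AMT1 3.33-fold (1.74, SE 0.22) and the lectin gene WSC3 2.91-fold (1.54, SE 0.24), each with all 3 root arrays above all 3 medium arrays. E5NT was 1.08 log2 higher (SE 0.34, adjusted p = 0.0193 by limma), a call that was lost without medium replicate 3 (0.88), without Arabidopsis 14 dpi replicate 1 (0.80) or 2 (1.03), with quantile normalization (0.98), in the authors' deposited table (1.01) and with slide as a random block (1.10). The effector candidate PIIN_08944 differed by -0.14 and was not called. TEF differed by 0.46 and was not called, and like FGB1 (-2.36) and E5NT (-6.04) it turned sign (-6.66) when scaling to all probes moved every gene by -7.12.

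PIIN_04582 rose 284-fold (8.15 log2, SE 0.27) and PIIN_01553 134-fold (7.06, SE 0.51), while PIIN_02853 fell 51.6-fold (-5.69, SE 0.47) and PIIN_05015 37.4-fold (-5.22, SE 0.27), with adjusted p between 1.24e-10 and 5.24e-07 by limma. PIIN_01553 was at 7.84 without Arabidopsis 14 dpi replicate 3, and normexp gave -4.71 for PIIN_02853 and -4.27 for PIIN_05015. Of 8562 genes measured in both groups, 1637 were called, 1157 higher and 480 lower on the root. Over all 10030 genes, 2056 were called, 1368 higher and 688 lower, of which 104 had no order, 218 were partly measured, and 6 higher and 91 lower were detected in only 1 group; 1998 had no overlap between replicates. Without a minimum difference 2116 genes measured in both were higher and 1796 lower (2342 and 2032 over all). The split among genes measured in both was 866 and 572 with quantile normalization, 857 and 586 in the authors' deposited table, 1539 and 358 with normexp, and 1 and 8560 when scaled to all probes. Over all genes it was 942 and 813, 950 and 900, 2586 and 377, and 3 and 10019 in the same order, and with slide as a random block 1539 genes measured in both were called.

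Colonisation of barley gave the largest count of called genes against medium, again with host and age differing together. The nuclease gene PIIN_02121 was 383-fold higher on barley roots than on medium (8.58 log2, SE 0.65, adjusted p = 3.13e-08 by limma), at 2.59 ± 1.28 against -5.99 ± 0.07 (SD, n = 3 each), and the difference was 9.32 without barley replicate 1. E5NT was 25.7-fold higher (4.69, SE 0.34), FGB1 21.6-fold (4.44, SE 0.56), WSC3 9.76-fold (3.29, SE 0.24) and AMT1 was 3.08 log2 higher (SE 0.22), all with no overlap between replicates. FGB1 was at 3.33 in the authors' deposited table. The effector candidate PIIN_08944 differed by -0.15 and was not called. TEF was at -0.77 and not called, and passed as lower with quantile normalization (-1.43), in the authors' deposited table (-1.18) and when scaling to all probes moved every gene by -1.68 (-2.45), with the same sign in each.

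PIIN_06258 rose 5943-fold (12.54 log2, SE 0.34) and PIIN_03736 2405-fold (11.23, SE 0.45), and PIIN_03915 fell 85.5-fold (-6.42, SE 0.18) and PIIN_09801 55.8-fold (-5.80, SE 0.28), with adjusted p between 1.39e-12 and 2.33e-10 by limma. PIIN_06258 was at 11.59 with quantile normalization and 11.01 in the authors' deposited table, PIIN_03736 at 10.19 and 10.48, and normexp gave 10.25 for PIIN_03736 and -5.79 for PIIN_03915. Of 7285 genes measured in both groups, 2824 were called, 1743 higher and 1081 lower on barley. Among the 5364 genes detected on all 12 arrays the split turned, with 877 higher and 1030 lower. Over all 10030 genes, 3914 were called, 2376 higher and 1538 lower, of which 275 had no order, 641 were partly measured, and 40 higher and 134 lower were detected in only 1 group; 3860 had no overlap between replicates. Within slide 3, which held the barley arrays and 2 medium arrays, 2912 genes measured in both were called, 1848 higher and 1064 lower, and a fixed slide block is the same comparison, since it sets aside medium replicate 3. On that slide the barley arrays were in row 1 and the medium arrays in row 2, so row and host were not separated. Without a minimum difference 2767 genes measured in both were higher and 2293 lower (3537 and 2910 over all). The split among genes measured in both was 1370 higher and 1468 lower with quantile normalization, 1348 and 1498 in the authors' deposited table, 2076 and 802 with normexp, and 577 and 4959 when scaled to all probes. Over all genes it was 1591 and 2402, 1581 and 2542, 4051 and 860, and 723 and 6804.

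**Figure D3:**
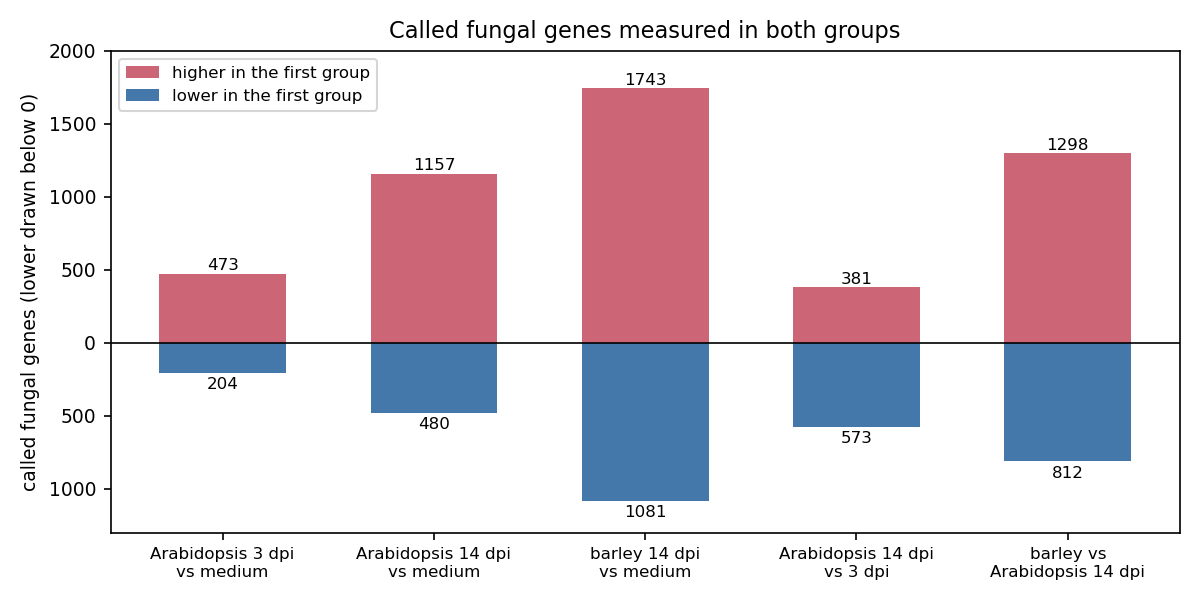
Fungal genes called by limma among those measured in both groups of each comparison, with the count higher in the group named first drawn above 0 and the count lower drawn below 0. Barley against medium had the most calls, 1743 higher and 1081 lower; under other scalings the splits shift as the text gives.

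Change during colonisation of Arabidopsis was followed by comparing 14 with 3 dpi, on arrays of the same slide. FGB1 had the largest rise of the genes measured at both times, 34.4-fold (5.10 log2, SE 0.56, adjusted p = 6.23e-06 by limma), followed by PIIN_07313 at 21.7-fold (4.44, SE 0.23). The FGB1 rise was 5.98 without Arabidopsis 14 dpi replicate 3 and 4.40 in the authors' deposited table. PIIN_11214 fell 39.5-fold (-5.30, SE 0.35, and -4.65 with normexp) and PIIN_09421 34.8-fold (-5.12, SE 0.33). AMT1 (1.53) and the nuclease gene PIIN_02121 (2.10) were also called higher, from 1 detected array of 3 at 3 dpi, and normexp ended both calls (0.34 and 0.50). The nuclease call was also lost without Arabidopsis 3 dpi replicate 3 (1.57) or 14 dpi replicate 2 (1.49), and the difference was 2.80 without 14 dpi replicate 3, 2.83 with quantile normalization and 3.29 in the authors' deposited table. WSC3 differed by 0.75, the effector candidate PIIN_08944 by -0.75 and E5NT by -0.53, and none was called. TEF was lower at 14 dpi, with a difference of -1.20 log2, a call that ended with quantile normalization (-0.66) and in the authors' deposited table (-0.49) and that, like the E5NT value (1.50), turned sign (0.83) when scaling to all probes moved every gene by 2.03. Arabidopsis RNA on the TEF probes stays open here too.

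Of 5537 genes measured at both times, 954 were called, 381 higher and 573 lower at 14 dpi. Over all 10030 genes, 2746 were called, 1160 higher and 1586 lower, of which 978 had no order and 450 were partly measured, while 360 were detected only at 14 dpi and called higher and 4 only at 3 dpi and called lower; 2699 had no overlap between replicates. Genes called against medium at 3 dpi tended back towards the medium level: of 457 higher ones measured in all 3 groups, 277 fell and 20 rose from 3 to 14 dpi, 247 were still called higher, and the median difference from medium went from 1.92 to 1.16. Of 204 lower ones, 78 rose and 4 fell, 65 were still called lower, and the median went from -1.28 to -0.60. Genes picked for a large difference at 3 dpi shift towards 0 through selection alone, and the share of the shift that this takes was not tested. For the higher genes, level signal from Arabidopsis RNA on the probes would also fall after scaling as fungal signal rises. The unscaled signal of the 473 genes called higher at 3 dpi rose by a median of 1.045 log2, against 2.40 for all measured genes. These sources were not separated. Without a minimum difference 1287 genes measured at both times were higher and 1448 lower (2618 and 2633 over all). The split among genes measured at both times was 244 higher and 698 lower with normexp and 4976 and 41 when scaled to all probes. Over all genes it was 1572 and 1043 with quantile normalization, 1726 and 1067 in the authors' deposited table, 326 and 3336 with normexp, and 8468 and 91 when scaled to all probes.

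Host dependence was addressed by comparing barley with Arabidopsis, both at 14 dpi. The nuclease gene PIIN_02121 was 32.3-fold higher on barley (5.01 log2, SE 0.65, adjusted p = 1.27e-05 by limma), E5NT 12.2-fold (3.61, SE 0.34), WSC3 3.35-fold (1.75, SE 0.24) and AMT1 2.53-fold (1.34, SE 0.22), each without overlap between replicates. The nuclease difference was 5.75 without barley replicate 1, 5.62 without Arabidopsis 14 dpi replicate 2 and 4.31 without replicate 3. FGB1 stood at 5.41 ± 0.86 on barley and 5.73 ± 1.53 on Arabidopsis (SD, n = 3 each), a difference of -0.32 with an SE of 0.56 that did not pass the test. Without Arabidopsis 14 dpi replicate 3, whose FGB1 signal was the lowest of the group, the difference was -1.20 and was called lower on barley. The effector candidate PIIN_08944 differed by -0.01. TEF was lower on barley, with a difference of -1.24 (SE 0.19) that was also called with quantile normalization (-1.60), with normexp (-1.27) and in the authors' deposited table (-1.28) and, like the FGB1 value (5.12), turned sign (4.21) when scaling to all probes moved every gene by 5.44.

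**Figure D4:**
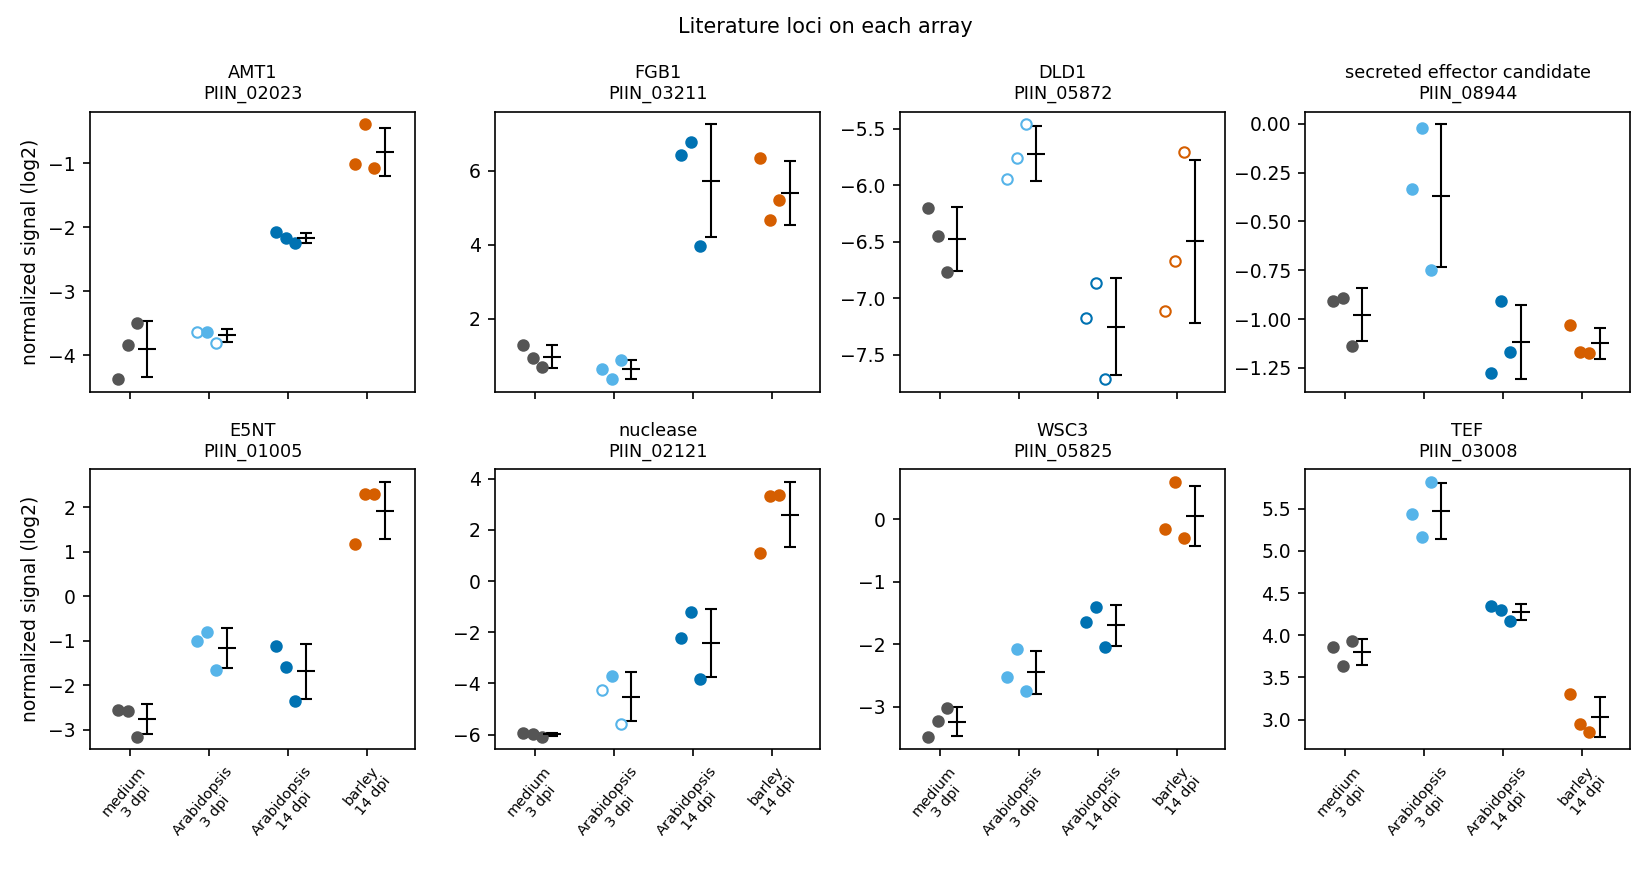
Normalized log2 signal of the 8 literature loci on each array, by group (filled: well above background; open: not; dash with bars: mean and SD, n = 3). FGB1 averaged 0.63 at 3 dpi and 5.73 at 14 dpi on Arabidopsis, and the nuclease gene averaged -5.99 on medium and 2.59 on barley; scaling to all probes moves every gene of a group alike, TEF included (5.47 on Arabidopsis at 3 dpi, 3.03 on barley).

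PIIN_07568 was 826-fold higher on barley than on Arabidopsis (9.69 log2, SE 0.27) and PIIN_06520 412-fold (8.69, SE 0.24). PIIN_07313, which had risen with time on Arabidopsis, was 105-fold lower on barley (-6.72, SE 0.23), at -3.46 ± 0.01 against 3.26 ± 0.21, and PIIN_09801 differed by -5.93 (SE 0.28). PIIN_07568 was at 8.73 in the authors' deposited table, and PIIN_06520 at 6.86 there and 7.89 with quantile normalization. Adjusted p for these 4 genes lay between 4.37e-12 and 5.18e-10 by limma. On barley replicate 3, which had the least fungal signal of its group, the scaled signal of PIIN_07568 was 6.001, against 5.437 and 5.175 on replicates 1 and 2. That of PIIN_06520 was 8.313, against 7.259 and 7.305. A gene falling with the fungal signal would stay level after scaling, so barley RNA on these 2 probes stays open. Of 7162 genes measured on both hosts, 2110 were called, 1298 higher and 812 lower on barley. Over all 10030 genes, 3288 were called, 1956 higher and 1332 lower, of which 269 had no order, 622 were partly measured, and 110 higher and 177 lower were detected on only 1 host; 3220 had no overlap between replicates. The hosts were on different slides, and with slide as a random block 2071 genes measured on both were called. Without a minimum difference 2477 genes measured on both were higher and 1879 lower (3244 and 2598 over all). The split among genes measured on both was 1094 and 1071 with quantile normalization, 1077 and 1107 in the authors' deposited table, and 7153 and 1 when scaled to all probes. Over all genes it was 1440 and 1812, 1441 and 1923, and 10015 and 1, and with normexp 1879 and 679.

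Genes of the fungus that changed on both hosts at 14 dpi were counted among 7145 genes measured on medium and both hosts. FGB1, AMT1, E5NT, WSC3 and the nuclease gene PIIN_02121 were among 619 genes called higher than medium on both hosts, where independent lists would share 192. The E5NT call on Arabidopsis was lost under several settings, as given above. Both hosts were sampled at 14 dpi and the medium at 3 dpi, so the age of the fungus alone could also make the lists agree. A further 212 were called lower on both, against 63.9 for independent lists. The differences from medium correlated across genes at 0.622 with a covariance of 0.941. Both comparisons used the same 3 medium arrays, and 100 simulations of unchanged groups against such shared controls gave a correlation of 0.50, a covariance of 0.0213 and 0 genes called on both. With no gene changed hardly any call can arise, so the 0 is no baseline for the shared genes. The simulated spread of the shared arrays gave little of the covariance. Its part in the count of shared genes was not measured. The 3 medium arrays were not divided between the comparisons, because 1 side would keep a single array, so part of the excess may come from the shared controls. Of the 831 genes called in the same direction, 376 also differed between hosts. 1815 genes were called on barley alone, and for 1174 of these the difference between hosts was itself called. For Arabidopsis alone the counts were 381 and 186. With quantile normalization 473 genes were higher and 273 lower on both hosts, and without a minimum difference 1234 and 1092.

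**Figure D5:**
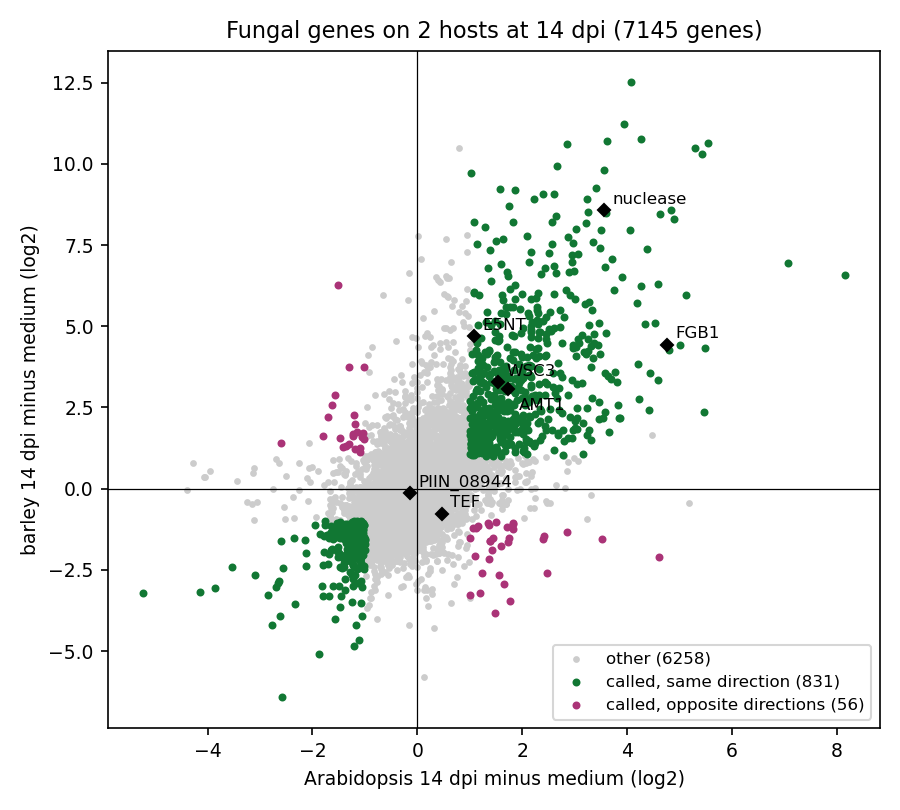
Log2 difference from medium of each fungal gene on Arabidopsis (horizontal) and barley (vertical) at 14 dpi, for 7145 genes measured in all 3 groups, with genes called in the same direction on both hosts (831) or in opposite directions (56) coloured and literature loci marked. E5NT and the nuclease gene lie at 4.69 and 8.58 on barley against 1.08 and 3.57 on Arabidopsis; scaling to all probes moves every gene, TEF included, by -7.12 along the horizontal and -1.68 along the vertical axis, which turns the sign of TEF on Arabidopsis and not on barley.

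Among the 5364 genes detected on all 12 arrays, 2324 were called against medium in at least 1 colonised group. 177 were higher and 41 lower in all 3. On barley 452 genes were called higher and 735 lower that had no call on Arabidopsis at either time, and 314 and 400 of these were themselves called in that direction between the hosts at 14 dpi.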

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

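The background test of genes not measured in both groups was chosen only after the results had been seen. So was the look at the genes with a high medium level at 14 dpi and on barley. So was the comparison with Arabidopsis probes on barley replicate 3. The rule for this comparison was revised with its values in view, and the gap between the quartiles was narrow (-1.30 and -1.23). No verdict is therefore drawn from it. The other tests here were written down before their results. For position on the array only the bound was, and not the interval required around the gap to it.

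Several fungal genes differed between times or hosts by a test of the difference itself. FGB1 (PIIN_03211) was higher at 14 than at 3 dpi on Arabidopsis by 5.10 log2, and TEF (PIIN_03008) was lower, at -1.20, or 0.83 when scaling to all probes moved every gene by 2.03. The TEF call between these times ended with quantile normalization and in the authors' deposited table (-0.49), and Arabidopsis RNA on the TEF probes stays open. Between barley and Arabidopsis at 14 dpi the nuclease gene PIIN_02121 differed by 5.01, E5NT (PIIN_01005) by 3.61, WSC3 (PIIN_05825) by 1.75, AMT1 (PIIN_02023) by 1.34 and TEF by -1.24, the last 4.21 when scaling to all probes moved every gene by 5.44. 56 genes were called higher than medium on 1 host and lower on the other, 23 higher and 33 lower on barley. Their calls lie at least 2 log2 apart against the same medium arrays, so that they were also called between the hosts follows from how they were chosen and is no separate test. In the data outside the main measurement, 18798 Arabidopsis probes were well above background on all 6 Arabidopsis arrays and on no medium array.

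On Arabidopsis at 3 dpi, 473 of the 677 called genes measured in both groups were higher than on medium, an excess seen only with the minimum difference of 1 log2, since without it 963 were higher and 1196 lower. Among 1705 genes chosen by a high medium level 30.4% of the called genes were higher (52 of 171), but the same genes leaned to falls at 14 dpi (76 higher, 243 lower) and on barley (130 higher, 597 lower) too, so that choice itself tilts the split and whether selection by detection makes the excess of rises stays open. The unscaled signal of the 473 genes rose from 3 to 14 dpi by a median of 1.04 log2 (1.045), against 2.40 for all measured fungal genes, and for 149 of them (31.5%, against 2.95% of all) by under 0.5, near the 0.0963 of the Arabidopsis probes. For this part, Arabidopsis RNA binding to fungal probes and an early fungal response cannot be told apart, because no array of Arabidopsis roots without the fungus was used here. Slide and host were confounded (663 calls with slide as a random block), and outside the genes measured in both groups 71.5% of calls (1097 of 1535) had no order at the background.

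Between barley and Arabidopsis at 14 dpi, 2110 genes measured on both hosts were called. A slide effect alone would leave barley close to the medium arrays of its own slide, but barley differed from these in the direction of the call by a median of 1.66 log2 (quartiles 0.97 to 2.65, 2098 genes), which argues against slide and scan as the only cause. Both differences used the same barley arrays and the hosts shared no slide, so what slide added to the calls was not measured. Barley and medium lay in different rows of that slide, so an effect of row was not separated in this test. Barley RNA binding to fungal probes stays open for the 1298 genes higher on barley (18.1% of those measured). On barley replicate 3, which had less fungal signal, they differed from replicates 1 and 2 by a median of -1.53 (quartiles -1.76 to -1.30), like all measured genes (-1.56). This passed the fall set beforehand for arguing against it. But the 402 Arabidopsis probes (1.47%) detected on both of those and on no medium array differed by -0.92 too (quartiles -1.23 to -0.53). These probes were chosen by detection on replicates 1 and 2 and not on replicate 3, which itself favours a fall there. The source of their signal is not known either. Whether barley RNA stayed level on replicate 3 was thus not shown, so a fall there cannot separate the causes. Compression by background was also argued against, since 29.0% of the genes far above background were called (1425 of 4921), against 29.5% of all. A response of the fungus to its host stays as a hypothesis, found and tested on the same data, and plant age and the excised root zone differed with the host.

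Fungal genes with consecutive locus numbers were often called in the same direction, in 490 pairs for barley against medium. 1000 shuffles of the calls along the loci gave 346 to 467 pairs with a mean of 412, which argues against chance order. Replicate deviations of consecutive loci correlated at 0.0709, below the 0.156 of the group differences that position on the array would need, but not clearly below 0.0782, 0.5 times that value and the bound set for arguing against it (gap -0.0148 to 0.0302), so position on the array cannot be told apart from neighbouring genes changing together. For Arabidopsis at 14 dpi against medium and between the Arabidopsis times the replicate deviations correlated more strongly than the differences (0.130 against 0.0967, 0.0797 against 0.0528), as position on the array would give, and for barley against Arabidopsis less (0.0692 against 0.137). Neighbouring genes that vary together between biological repetitions would correlate in this way too, so replicate deviations cannot single out position. The other pair counts were 206 for Arabidopsis at 14 dpi against medium (shuffles 110 to 196), 307 for barley against Arabidopsis (190 to 266), 29 for Arabidopsis at 3 dpi against medium (15 to 45) and 50 between the Arabidopsis times (29 to 70).

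Each comparison had 10 splits of its 6 arrays into 3 and 3, too few for a share under 0.05, and in each 1 split, the real one, gave as many calls. The real split called 2212, 2056, 3914, 2746 and 3288 fungal genes (Arabidopsis at 3 dpi, Arabidopsis at 14 dpi and barley against medium, then Arabidopsis at 14 against 3 dpi, then barley against Arabidopsis) and 709 Arabidopsis genes. The highest of the other splits called 1 gene for Arabidopsis at 3 dpi against medium and 0 in each of the others. These splits put arrays of both groups on each side, which widens the spread where groups differ. Few calls could arise there, so their low counts are no baseline.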

How the results depend on the processing

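The counts of genes well above background in both groups, the percentile over fungal probes and all alternatives for the Arabidopsis genes were chosen after seeing the data; the others were planned. Counts follow the order Arabidopsis at 3 dpi, Arabidopsis at 14 dpi and barley against medium, Arabidopsis at 14 against 3 dpi, and barley against Arabidopsis. Of the recomputed fungal counts under settings other than a left-out array, 123 stayed within 1.5 times and 34 did not. Of the values of named fungal genes 699 kept their call or stayed uncalled, and 10 lost and 11 gained a call with the same sign. A further 21 turned sign and were called in the main fit or under the setting. Signs were not compared for values that stayed uncalled. DLD1 (PIIN_05872), below background on every root array, got no value under any setting. All 69 fungal counts with an array left out stayed within 1.5 times, and so did all 6 Arabidopsis ones. Signal over background is a limit: on Arabidopsis at 3 dpi about 50% of fungal probes gave no usable level, so falls there can only be seen for genes bright on medium. The planned gene lists by product, with all their alternatives, were not run. The cause was not tested, except where the construction of a setting shows it.

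Without a minimum difference more genes were called by construction, 4357, 4374, 6447, 5251 and 5842 over all genes, 2159, 3912, 5060, 2735 and 4356 among genes measured in both groups, 2326 in the same direction on both hosts and 4069 Arabidopsis genes. With only genes well above background in both groups the counts were 677 (Arabidopsis at 3 dpi against medium), 954 (between the Arabidopsis times) and 2110 (between hosts). With only genes on all 12 arrays, fewer genes were tested, and 594, 847, 1907, 872 and 1456 were called, the 847 also among genes measured in both. Without a filter 3943 (3 dpi against medium), 3227 (14 dpi against medium) and 4418 (between the Arabidopsis times) were called, and with normexp 4345 (3 dpi against medium).

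Scaling to all probes, which shifts every gene of a comparison by a constant, called 10024, 10022, 7527, 8559 and 10016 genes, and 5539, 8561, 5536, 5017 and 7154 among those measured in both. By the same shift, values turned sign at 3 dpi against medium for PIIN_07267 (-0.29), PIIN_02222 (-0.69), PIIN_02023 (-8.94), PIIN_08944 (-8.54), PIIN_01005 (-7.54), PIIN_02121 (-7.68), PIIN_05825 (-8.36) and PIIN_03008 (-7.49, in full -7.485). At 14 dpi against medium they did for PIIN_01553 (-0.06, in full -0.0577), PIIN_02023 (-5.39), PIIN_03211 (-2.36), PIIN_01005 (-6.04), PIIN_02121 (-3.55), PIIN_05825 (-5.58) and PIIN_03008 (-6.66). Between the Arabidopsis times they did for PIIN_08944 (1.28), PIIN_01005 (1.50) and PIIN_03008 (0.83), and between hosts for PIIN_03211 (5.12), PIIN_08944 (5.44) and PIIN_03008 (4.21).

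With an array left out, counts over all genes ranged from 1971 to 2334, 1779 to 2320, 3786 to 4024, 2613 to 2838 and 3176 to 3381. Among genes measured in both groups they ranged from 647 to 728, 1447 to 1886, 2748 to 2912, 939 to 1032 and 2086 to 2181, in the same direction on both hosts from 745 to 959, and for Arabidopsis genes from 549 to 755. Slide as a random block called 1998 (3 dpi against medium), 1853 (14 dpi against medium) and 3077 (between hosts) over all genes. With quantile normalization 746 genes were called in the same direction on both hosts. Arabidopsis calls were 699 with quantile normalization, 754 with medium-detected probes kept and 689 without an intensity trend.

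The replicate numbers did not pair the arrays: deviations of same-numbered arrays correlated over 0.1 in 6 of 18 pairs (from -0.345 to 0.339), and 6 of 12 arrays correlated best with their own number. With a replicate block 2217, 2066, 3917, 2745 and 3292 genes were called, 677, 1635, 2824, 954 and 2107 among those measured in both, and 665 Arabidopsis genes (same-numbered arrays there -0.239 to 0.0179).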

Other observations

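All tests of Arabidopsis genes in this part were chosen after the array was found to hold Arabidopsis probes.

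The roots themselves could be followed from 3 to 14 dpi through the Arabidopsis probes. Of 5 tested genes linked to jasmonate and ethylene defence, 3 rose: VSP2, a vegetative storage protein gene induced by jasmonate, by 1.70 log2 (SE 0.25, adjusted p = 0.00537 by limma), the ethylene response factor gene ERF1 by 1.49 (SE 0.24) and the basic chitinase gene PR3 by 1.44 (SE 0.08). VSP1 (0.36) and JAZ1 (0.25) were not called, PR4 and AOS were left out because they were detected on a medium array, and LOX2, LOX3 and PDF1.2a were too dim. The list as a group was called upward with a preset correlation (camera adjusted p = 0.002), and not with an estimated one (adjusted p = 0.213). In pattern-triggered immunity 2 of 7 genes rose, the flagellin receptor gene FLS2 by 1.97, not detected on all 6 arrays, and FRK1 by 1.49, a call lost with a replicate block and without Arabidopsis 3 dpi replicate 1 (1.52) or 3 (1.11) or 14 dpi replicate 1 (1.56), 2 (1.68) or 3 (1.24). WRKY40 was at -0.68 and not called (list adjusted p = 0.491). Of 8 tested genes of indole glucosinolate and camalexin synthesis, CYP71A13 rose by 2.61, not detected on all 6 arrays, and PAD3 at 0.90 was called only without 14 dpi replicate 3 (1.31), with a list adjusted p of 0.259. In salicylate-linked defence ICS1 (0.62) and NPR1 (-0.07) were not called, and PR1, PR2 and PR5 were too dim.

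Among nutrient genes, the phosphate starvation gene SPX3 rose by 1.90 log2 (SE 0.15, adjusted p = 0.000601 by limma), while the transporter gene PHT1;4 (-0.81) and PHO1;H1 (-0.98) were not called, and PHO1;H1 passed the threshold with quantile normalization and without 3 dpi replicate 2 (-1.02) or 14 dpi replicate 1 (-1.04) or 3 (-1.17). Over its 7 tested genes, which went both ways, no shift of the list was detected (adjusted p = 0.798). None of 11 nitrogen genes was called, with the nitrate transporter gene NRT2;1 and the ammonium transporter gene AMT2;1 each at 0.40 (list adjusted p = 0.215), and none of 6 endodermis and suberin genes (adjusted p = 0.215). None of 3 tested photosynthesis genes was called, at a median of -0.68, with RBCS3B called only without 3 dpi replicate 3 (-3.72). Their SD at 3 dpi was 3.25 log2 for RBCS3B, 1.84 for RBCS1A and 0.98 for LHCA1, and at 14 dpi 1.35, 0.76 and 0.55. An uneven share of shoot tissue among the replicates therefore stays open. CAB1 and CAB3 were left out because they were detected on a medium array. In all, 709 of 19172 Arabidopsis genes (3.70%) were called, 449 higher and 260 lower at 14 dpi, and 521 of them, 307 higher and 214 lower, were measured on all 6 arrays. Arrays of a time point correlated at 0.986 or more. Roots without the fungus were not used here and the plants were older at 14 dpi, so colonisation and age are not separated, and the times were in different rows of the slide.

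Of the 274 Arabidopsis probes brightest on the Arabidopsis arrays, 51.5% were well above background on medium replicate 1, 18.2% on replicate 2 and 9.49% on replicate 3, and 26.6%, 26.3% and 24.1% on barley replicates 1, 2 and 3. Of the dimmer 13693 Arabidopsis probes, 1.45 to 2.90% were. The signal of the 274 probes on these arrays was a median of 11.8 to 13.2 log2 below the Arabidopsis arrays (differences of -11.8 to -13.2).

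Barley replicate 3 had the lowest share of fungal probes well above background of the group, 60.5% against 68.3% and 70.5%. Among called genes with at least 2 measured probes, probes had opposite signs in 0 of 24, 1 of 63, 5 of 64, 0 of 31 and 0 of 48 genes, for Arabidopsis at 3 dpi, Arabidopsis at 14 dpi and barley against medium, for Arabidopsis at 14 against 3 dpi, and for barley against Arabidopsis. PIIN_09421, lowest in the fungus on Arabidopsis at 14 dpi, averaged 3.20 log2 on medium, 4.36 and -0.76 on Arabidopsis at 3 and 14 dpi, and 3.75 on barley.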
